A study of Homo sapiens with 6 samples.

How the data were processed

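The series holds 6 mRNA sequencing libraries of CAL27 cells, 3 treated with PBS and 3 with 30 mM metformin for 48 h. Per the labels' protocols, total RNA was made into libraries with a VAHTS mRNA-seq kit, and the series design names an Illumina HiSeq X 10 and reads of 150 bp. The authors deposited 1 FPKM value per gene and library, per the file headers, and no read counts were used here. Per the submitters' processing notes the genome build was GRCh38. The aligner, the quantification tool, its strand setting and the annotation release are not given in the sources used here.

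The files list 58243 versioned Ensembl gene identifiers without symbols. Symbols, gene types and coordinates were taken from GENCODE release 29 (GRCh38) by the identifier without its version, which named 57980 genes, 55619 of them with an identical version, and left 263 unnamed. In all, 27781 genes were listed at 0 in every library. The 37 genes of mitochondrial DNA were among them, although cells express these at high levels, so a listed 0 is not read here as absence. FPKM divides by the total of mapped fragments, so a gene's value also depends on all other genes, and a large change in abundant transcripts moves the rest.

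FPKM tables give no depth directly. The low values of a gene were spaced in steps of 1 fragment, and the ratio of these steps between libraries gave depths of 0.957 to 1.08 relative to PBS replicate 1. With exonic lengths of GENCODE 29 single-transcript genes, the steps corresponded to 7820000 to 8820000 fragments, which is an estimate. Between 22790 and 24193 genes were above 0 per library, and between 12982 and 13613 reached 1 FPKM. No pair of libraries shared more than 2 identical values above 0 among the 13437 tested genes.

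The tested genes were the 13437 with a mean of at least 1 FPKM over the 6 libraries. Values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with group as the only term and no replicate block. Limma's moderated test is two-sided, and p-values were adjusted by the method of Benjamini and Hochberg over the tested genes, with a threshold of 0.05. The design was written for normalized values before the data were examined, as were the gene lists, the alternatives and the rule for named genes. On simulated data with the real levels and spread of the 13437 genes and 50 genes changed at each size, the fit recovered 40% of changes of 1.5-fold, 56% of 2-fold and 80% of 4-fold. Of its calls 3.16% were false, and it made 0 calls when nothing was changed. With so few genes changed, the adjustment was stricter there than in the real comparison, so these shares are not its detection rates.

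Of 34 fixed lists, 30 had at least 5 tested members and were tested with camera, with the correlation preset at 0.01 and, for comparison, estimated from the data. The lists were written from textbook knowledge for this cell line and drug, and include markers of other cell types and of RNA quality. The text names the 12 largest rises and 12 largest falls among genes that passed, whose groups did not overlap and whose higher group averaged at least 5 FPKM, leaving out clone-based names and pseudogenes. It also names 4 passing members of each called list and 2 of each other list with the largest changes, and 6 genes of the AMPK kinase and of metformin transport. Some genes that the rule selects are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

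Exon overlaps between genes were computed with BEDTools 2.31.1, and other calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. Of 118 named genes, 30 share exon bases with another gene above the level filter. The alternatives were other pseudocounts, other level filters, rescaling to a fixed sum, median-of-ratios and quantile scaling, a replicate block, limma without the trend or with a robust prior, other tests of the lists, and each library left out in turn. After the data were seen, 2 alternatives were added: leaving out both libraries numbered 3, and testing protein-coding genes alone. The alternative that left out mitochondrially encoded genes changed nothing beyond the rescaling, since these genes were listed at 0.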

Results

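Transcript levels were measured by mRNA sequencing in CAL27, an established cell line from a squamous cell carcinoma of the human tongue. The cells were cultured for 48 h with 30 mM metformin, a biguanide used to lower blood glucose, or with the phosphate-buffered saline (PBS) vehicle. No other dose was included, so changes at lower doses were not measured. Each group held 3 libraries. The deposited FPKM values (fragments per kilobase of transcript, scaled to the number of mapped fragments) summed to between 200842 and 208899 per library. From the steps in which low values were spaced, a library was estimated to hold between 7820000 and 8820000 counted fragments, and no group was deeper than the other throughout. Levels below are the mean ± SD of the 3 libraries of a group in FPKM, folds are ratios of those means, and log2 changes are metformin minus PBS on the log2(FPKM + 1) scale, which understates the change of genes with low values.

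The comparison of metformin with PBS addressed which transcripts change in head and neck squamous carcinoma cells under metformin, the drug whose effect on chemosensitivity the series was made to study. Metformin-treated cells had higher levels of stress-response transcripts of the ATF4 pathway, among them DDIT3 and GDF15, and of squamous differentiation, early-response and ribosomal protein genes. The calls of the squamous and ribosomal protein lists were lost with an estimated correlation between members (adjusted p = 0.147 and 0.459). The cells had lower levels of transcripts for DNA replication, mitosis, glycolysis, the tricarboxylic acid cycle and cholesterol synthesis, and of the basal keratins KRT14 and KRT5. Of 13437 tested genes, 7549 (56.2%) differed at an adjusted p below 0.05 by limma with Benjamini-Hochberg adjustment, 4169 of them higher and 3380 lower with metformin. A change of at least 1 on the log2(FPKM + 1) scale, 2-fold on that scale, was seen in 1512 of these, 875 higher and 637 lower. That scale leaves out genes with low values whose means differ more than 2-fold, and with a pseudocount of 0.01 the count was 2320. Among genes with a mean of at least 5 FPKM, 427 were higher and 450 lower by that much. The median SE of a log2 change was 0.0993. In 8659 genes (64.4%, against 10% by chance) the values of the groups did not overlap. The first principal component held 76.5% of the variance and separated the groups. Pearson correlations of log2 values across genes were 0.974 to 0.979 between libraries of one group and 0.881 to 0.888 between groups. The labels do not say that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

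**Figure D1:**
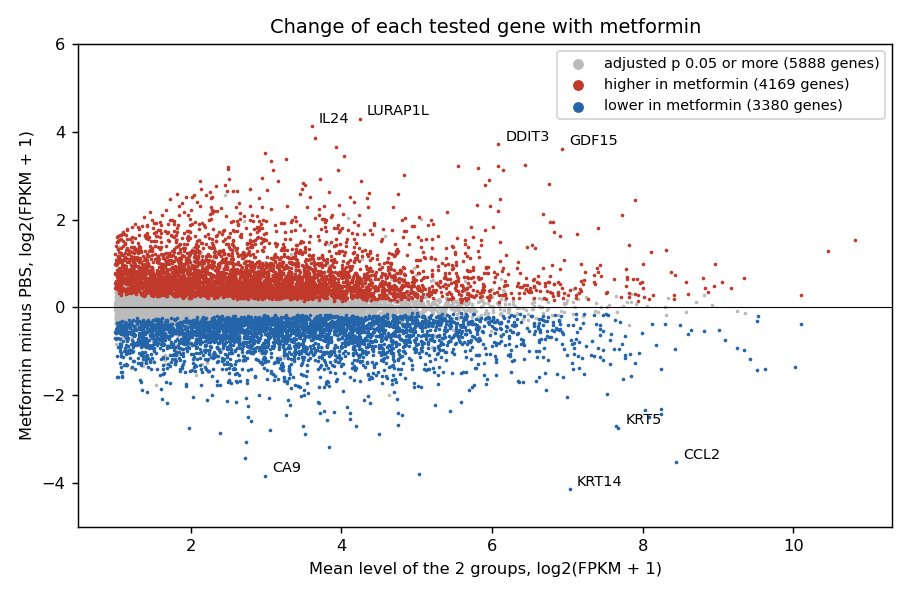
Each point is 1 of the 13437 tested genes, with the mean level of both groups on the x axis as log2(FPKM + 1) and the change with metformin on the y axis as a difference of log2(FPKM + 1). Red points (4169 genes) were higher and blue points (3380 genes) lower with metformin at an adjusted p below 0.05 by limma, and grey points (5888 genes) did not pass.

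Among the 12 genes with the largest rises on the log2(FPKM + 1) scale was LURAP1L (ENSG00000153714.5, chromosome 9, 12775021 to 12822131 in GRCh38), from 0.827 ± 0.141 to 35.0 ± 3.38 FPKM (42.3-fold), a log2 change of 4.30 (SE 0.10). IL24, a cytokine of the IL-10 family, rose 67.8-fold from 0.324 ± 0.181 to 22.0 ± 1.35. DDIT3 (ENSG00000175197.11, chromosome 12, 57516588 to 57521737), which encodes the stress transcription factor CHOP, rose 14.6-fold from 8.55 ± 0.0554 to 125 ± 11.4. GDF15 (ENSG00000130513.6, chromosome 19, 18374731 to 18389176), a secreted cytokine of the TGF-beta superfamily, rose 12.8-fold from 17.4 ± 0.836 to 224 ± 11.5, a log2 change of 3.61 (SE 0.06, limma adjusted p = 9.13e-07). BEX2 rose 16.5-fold. UPP1, a uridine phosphorylase, rose 10.1-fold to 156 ± 10.7, and AREG, the epidermal growth factor receptor ligand amphiregulin, rose 9.98-fold to 122 ± 7.95. The inflammatory cytokine IL6 rose 9.79-fold from 10.2 ± 0.563 to 100.4 ± 5.51. MAP1B, a microtubule-associated protein, went from 0.148 ± 0.0730 to 9.17 ± 0.875. ERV3-1, an endogenous retroviral envelope gene, rose 10.2-fold to 83.3 ± 1.29. DEFB4A, an epithelial defensin, had 14.2 ± 1.35 FPKM with metformin against 0.537 ± 0.429, a value that is uncertain because the genome carries a near-identical copy, DEFB4B.

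Among the 12 genes with the largest falls on that scale, 3 were keratins of the basal epithelial layer. KRT14 (ENSG00000186847.5, chromosome 17, 41582279 to 41586921) fell 19.1-fold from 246 ± 17.4 to 12.9 ± 0.275 FPKM, a log2 change of -4.15 (SE 0.06, limma adjusted p = 9.13e-07). KRT15 fell 11.1-fold from 19.2 ± 1.89, and KRT5 (ENSG00000186081.11, chromosome 12, 52514575 to 52520687), the partner of KRT14 in keratin filaments, fell 6.77-fold from 355 ± 6.04 to 52.5 ± 4.18. The chemokine CCL2 was lower by 11.8-fold, from 640 ± 59.5 to 54.1 ± 0.824, and CXCL1, a neutrophil-attracting chemokine, by 6.66-fold, from 346 ± 23.9 to 51.9 ± 3.44. CA9, a carbonic anhydrase induced in hypoxia, had 16.7, 13.3 and 11.4 FPKM in the PBS libraries and was listed at 0, 0.0354 and 0.0350 with metformin, a log2 change of -3.84 (SE 0.14). STC1, which encodes stanniocalcin, had 5.95, 6.71 and 4.95 with PBS and was listed at 0, 0.0286 and 0 with metformin. LY6D, a keratinocyte surface antigen, fell 17.2-fold from 59.8 ± 4.35. OLFM4, which encodes olfactomedin 4, fell from 11.1 ± 0.905 to 0.127 ± 0.0711. PLAT, the tissue plasminogen activator gene, fell 13.6-fold, RRM2, a ribonucleotide reductase subunit, 9.04-fold, and ALDOC, a glycolytic aldolase, 12.6-fold. DDIT3, ERV3-1, IL6, CA9, LY6D, RRM2 and ALDOC share exon bases with another listed gene above the level filter. Among genes named below, so do ACAT2, FDPS, SREBF1, NDUFB9, NDUFB8, NDUFA11, ATP5F1A, ANGPTL4, DLD, TYMS and KIF20A. The same holds for TNFRSF10B, RAD54L, FANCI, ERCC2, BCL2L1, SLC7A11, MAP1LC3B, NOP56, PA2G4, TGFB2 and HSP90AA1. Fragments of such genes cannot be told apart where counting did not use strand, which the sources used here do not state, or where both genes lie on one strand.

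**Figure D2:**
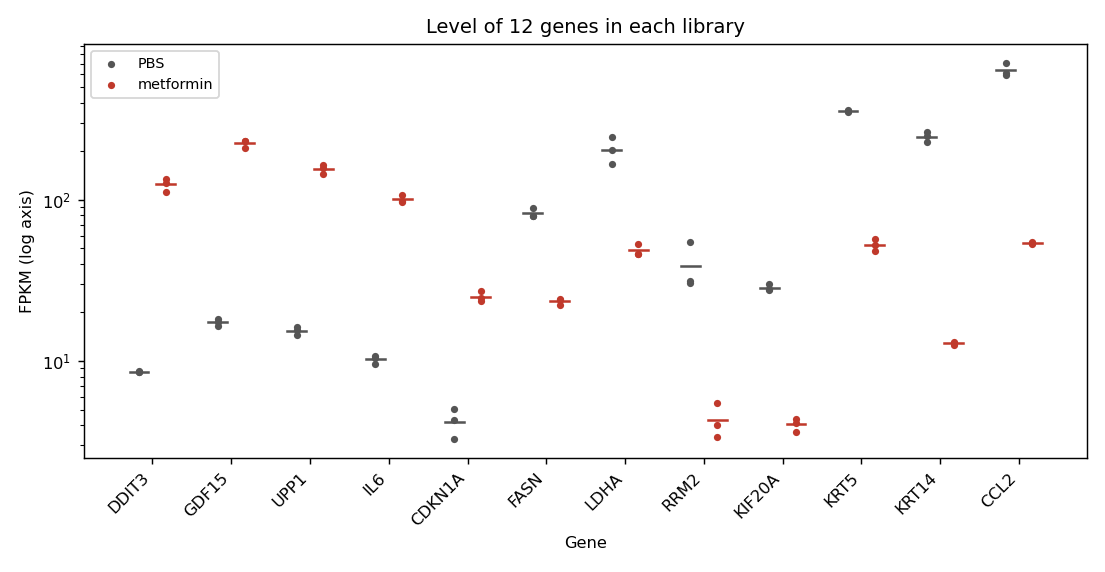
FPKM (log axis) of 12 genes in each library, with PBS in grey and metformin in red, where points are libraries and short lines are group means. DDIT3, GDF15, UPP1, IL6 and CDKN1A were higher in all 3 metformin libraries, and FASN, LDHA, RRM2, KIF20A, KRT5, KRT14 and CCL2 were lower.

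Gene lists fixed before the data were examined were tested against the other genes with camera, a competitive test that presets the correlation between members at 0.01, with Benjamini-Hochberg adjustment over the 30 lists that had at least 5 tested members. Camera called 17 lists, 6 higher and 11 lower. With a correlation estimated from the data, 9 of these calls held and 8 did not, and the p for each list that did not hold is given with it. Those that held lay close to the threshold, with a camera adjusted p of 0.0314 for the ATF4 list and 0.0448 for each of the other 8. The far lower values printed below for these lists thus depend on running camera with a preset correlation. A higher correlation between members does not account for every difference. Among lists that held, the estimate was below 0.01 for ATF4 (-0.0214), the tricarboxylic acid cycle (-0.0383), immediate early genes (-0.0074) and ribosome biogenesis (0.00504). Of those that did not hold, it was below 0.01 for p53 targets (-0.0222) and fatty acid synthesis (0.00299). In the other called lists it was above 0.01. Member counts adjusted over the list alone were identical to the counts over all genes, except in the 5 lists where both are given.

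Transcripts of the ATF4 pathway, which raises amino acid synthesis and transport under stress, rose together. Of 36 tested members, 32 were higher and 0 lower, with a median log2 change of 0.94 (camera adjusted p = 2.56e-12). Besides DDIT3 and GDF15, TRIB3, a pseudokinase induced by CHOP, rose 9.65-fold from 13.1 ± 0.356 to 127 ± 42.6, and NUPR1, a stress-induced nuclear protein, rose 12.9-fold from 1.15 ± 0.126 to 14.8 ± 0.866. ER chaperone and unfolded protein response genes moved both ways, with 9 of 22 higher and 8 lower (camera adjusted p = 0.667). The stress sensor ERN1 rose 4.54-fold to 10.1 ± 0.560, whereas PDIA4, a disulfide isomerase of the ER, fell 2.91-fold from 172 ± 1.79 to 59.1 ± 3.20. The median of this list was 0.13 and its mean -0.01, the sign that camera gave. Immediate early and AP-1 genes were higher in 11 of 18 and lower in 1 (median 0.69, camera adjusted p = 0.000219). The phosphatase genes DUSP1 and DUSP5 rose 6.22-fold and 5.29-fold, and the AP-1 subunit gene JUN rose 2.96-fold from 28.8 ± 1.6 to 85.3 ± 2.58. MAFF, a small MAF transcription factor, rose 2.85-fold. Heat shock protein genes were lower in 11 of 15 and higher in 1, with 12 lower when adjusted over the list alone (median -0.50, camera adjusted p = 1.57e-05, and adjusted p = 0.147 with an estimated correlation). The cytosolic chaperone gene HSP90AB1 fell 2.28-fold from 957 ± 21.2 to 420.2 ± 9.42, and HSP90AA1, HSPA8 and HSPB1 fell between 1.94-fold and 2.23-fold. NRF2 targets and antioxidant genes gave 12 higher and 8 lower of 23 (camera adjusted p = 0.383), among them OSGIN1, an oxidative-stress-induced gene, 5.36-fold higher, and SLC7A11, the cystine transporter, 3.91-fold higher. Autophagy and lysosome genes gave 12 higher and 5 lower of 25 (camera adjusted p = 0.0868), with WIPI1 5.86-fold and MAP1LC3B 4.32-fold higher, both of autophagosome formation.

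Glycolysis genes gave 15 lower and 2 higher of 21, with 16 lower when adjusted over the list alone, and a median log2 change of -0.87 (camera adjusted p = 6.73e-07). LDHA, lactate dehydrogenase A, fell 4.21-fold from 205 ± 38.8 to 48.6 ± 4.17, PGK1, phosphoglycerate kinase, 3.24-fold from 145 ± 4.06, and GPI, glucose phosphate isomerase, 2.91-fold. Tricarboxylic acid cycle genes were lower in 16 of 19 and higher in 0 (median -0.56, camera adjusted p = 9.04e-08). IDH2, the mitochondrial isocitrate dehydrogenase, fell 3.87-fold from 21.2 ± 2.12 to 5.48 ± 0.945, SUCLG2 fell 2.72-fold and DLD 2.26-fold. MDH1, which encodes the cytosolic rather than the mitochondrial malate dehydrogenase, was on the list and fell 2.17-fold. Nuclear-encoded genes of respiratory complex I, the complex that metformin is known to inhibit, were lower in 23 of 37 and higher in 1 (median -0.32, camera adjusted p = 0.000219, and adjusted p = 0.338 with an estimated correlation). NDUFV1 fell 1.78-fold, NDUFB8 1.86-fold and NDUFA11 1.70-fold. NDUFB8 shares exon bases on its own strand with AL133352.1, which had 5.445 FPKM with PBS and 12.64 with metformin. NDUFA11 does so with AC024592.3, which had 2.018 and 1.028. Fragments of shared bases cannot be told apart, so these folds are uncertain. NDUFB9 fell from 33.8 ± 3.68 to 18.8 ± 5.52 (log2 change -0.84, limma adjusted p = 0.00837), a call that was lost without both libraries numbered 3 (adjusted p = 0.0685). Genes of complexes II to V were lower in 21 of 38 and higher in 0 (median -0.25, camera adjusted p = 3.9e-06, and adjusted p = 0.218 with an estimated correlation). SDHA of complex II fell 2.37-fold, and ATP5MC3, ATP5F1A and ATP5F1B of the ATP synthase fell between 1.98-fold and 2.31-fold. The 13 protein genes encoded by mitochondrial DNA were listed at 0 in every library, so their levels could not be compared.

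Cholesterol synthesis and uptake genes were lower in 20 of 25 and higher in 0, with 21 lower when adjusted over the list alone (median -0.73, camera adjusted p = 3e-07). MVD, mevalonate diphosphate decarboxylase, fell 3.02-fold from 12.1 ± 1.35 to 4.01 ± 0.422, ACAT2 2.14-fold and FDPS, farnesyl diphosphate synthase, 1.97-fold. Fatty acid synthesis genes gave 7 lower and 2 higher of 12 (median -0.26, camera adjusted p = 0.0286, and adjusted p = 0.155 with an estimated correlation). FASN, fatty acid synthase, fell 3.52-fold from 82.5 ± 5.10 to 23.5 ± 1.03, the desaturase SCD 2.67-fold from 195 ± 7.91, and SREBF1, a transcription factor of lipid synthesis, 2.64-fold. MLXIPL, the carbohydrate-responsive transcription factor ChREBP, rose 5.91-fold from 0.311 ± 0.187. The listed targets of hypoxia-inducible factor gave 5 higher and 6 lower of 20 and were not set apart from other genes (camera adjusted p = 0.469). This list left out LDHA, PGK1 and GPI, which were counted under glycolysis, and STC1, so its result does not speak for them. CA9 fell, as given above, and ANGPTL4, an inhibitor of lipoprotein lipase, rose 8.04-fold to 17.6 ± 1.81.

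The cell cycle lists had the lowest medians of the 30 tested lists. Mitosis and G2/M genes were lower in 36 of 37 and higher in 0, with a median log2 change of -1.49 (camera adjusted p = 2.66e-20). KIF20A, a mitotic kinesin, fell 7.05-fold to 4.04 ± 0.393, DLGAP5 6.20-fold, the mitotic kinase gene PLK1 5.58-fold and HMMR 4.84-fold. DNA replication and G1/S genes were lower in 34 of 38 and higher in 1 (median -1.07, camera adjusted p = 1.41e-14). Besides RRM2, the helicase subunit gene MCM6 fell 5.85-fold from 44.4 ± 0.858 to 7.58 ± 0.894, TYMS, thymidylate synthase and the target of 5-fluorouracil, fell 4.98-fold from 61.2 ± 1.84 to 12.3 ± 1.73, and TK1, thymidine kinase, fell 4.68-fold. Homologous recombination and Fanconi anaemia genes, which repair double-strand breaks and interstrand crosslinks, were lower in 18 of 27 and higher in 1 (median -0.59, camera adjusted p = 4.5e-06). RAD54L fell 3.03-fold, FANCI 2.24-fold, FANCE 2.30-fold and RAD51AP1 2.07-fold. Nucleotide excision and mismatch repair genes gave 3 higher and 5 lower of 18 (camera adjusted p = 0.470), with the helicase gene ERCC2 2.06-fold lower.

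Target genes of p53 were higher in 12 of 21 and lower in 2 (median 0.44, camera adjusted p = 0.0286, and adjusted p = 0.147 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 5.96-fold from 4.21 ± 0.870 to 25.1 ± 1.72, GADD45A, a growth arrest gene, 5.16-fold to 103 ± 6.57, and the death receptor gene TNFRSF10B 2.42-fold. FDXR, ferredoxin reductase, fell 2.67-fold. BCL2 family and caspase genes gave 8 higher and 8 lower of 28, with 9 lower when adjusted over the list alone (camera adjusted p = 0.514). BCL2L1, which encodes the survival protein BCL-XL, rose 3.06-fold from 16.6 ± 0.751 to 50.9 ± 1.08, and BCL2A1, another survival protein gene, fell 4.18-fold.

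Ribosome biogenesis and MYC target genes were lower in 18 of 32 and higher in 1 (median -0.29, camera adjusted p = 0.000134). NOP56 of the small nucleolar ribonucleoprotein fell 2.13-fold, SRM, spermidine synthase, 2.04-fold, NCL, nucleolin, 1.94-fold from 162 ± 4.56 to 83.4 ± 3.22, and PA2G4 1.69-fold. The antisense gene AC034102.4, which overlaps PA2G4, had 103 FPKM with PBS and 54.8 with metformin, against 105 and 62.5 for PA2G4 itself. Ribosomal protein genes were higher in 48 of 67 and lower in 4, with 5 lower when adjusted over the list alone (median 0.34, camera adjusted p = 3.9e-06, and adjusted p = 0.459 with an estimated correlation). RPS27 rose 1.75-fold from 241 ± 22.4 to 423 ± 3.85, and RPL37, RPL26 and RPL21 rose between 1.66-fold and 1.72-fold. Ribosomal protein genes have many pseudogenes with which they can share fragments.

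Squamous differentiation genes were higher in 12 of 17 and lower in 2 (median 1.17, camera adjusted p = 0.00333, and adjusted p = 0.147 with an estimated correlation). The cornified envelope genes SPRR2D and SPRR2A rose 15.9-fold and 20.1-fold, to 12.7 ± 1.78 and 6.88 ± 0.825, and LCE3D was listed at 0 in every PBS library and at 3.60, 2.90 and 4.05 with metformin. KLK7, a protease of the upper epidermis, rose 7.57-fold. These genes lay mostly at low levels, and the call was lost when genes were required to average at least 5 FPKM (adjusted p = 0.183). Basal keratinocyte and stem-like genes gave 10 lower and 6 higher of 22 (camera adjusted p = 0.186), led by KRT14 and KRT15. Epithelial-mesenchymal transition genes gave 11 higher and 5 lower of 20 (camera adjusted p = 0.354), with the growth factor gene TGFB2 4.76-fold higher and the matrix gene TNC 3.12-fold higher, from 57.5 ± 4.04 to 179 ± 2.65.

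Interferon-stimulated genes were higher in 15 of 27 and lower in 2 (median 0.54, camera adjusted p = 0.00417, and adjusted p = 0.459 with an estimated correlation). IFI27, IFI44L and IFI6 rose 3.58-fold, 3.57-fold and 2.58-fold, while the chemokine CXCL10 fell 10.3-fold from 10.5 ± 1.30 to 1.02 ± 0.214. Targets of NF-kappaB and inflammatory cytokines gave 8 higher and 12 lower of 25 (camera adjusted p = 0.1), and spanned the rise of IL24 and the fall of CCL2.

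Components of the AMPK and mTOR pathways, which sense cellular energy and nutrients, gave 11 higher and 3 lower of 20 (median 0.22, camera adjusted p = 0.0743). IRS2, an insulin receptor substrate, rose 4.53-fold from 2.42 ± 0.302, and PRKAB2, a regulatory AMPK subunit, 2.45-fold. The catalytic AMPK subunit gene PRKAA1 fell from 15.4 ± 0.391 to 11.3 ± 0.707 FPKM, a log2 change of -0.42 (SE 0.06, limma adjusted p = 0.00161). PRKAA2, the gene of the other catalytic subunit, averaged 0.455 FPKM with PBS and 0.713 with metformin, below the level filter, and was not tested. Drug transporter and detoxification genes gave 2 higher and 5 lower of 13 (camera adjusted p = 0.160). The efflux pump gene ABCC3 rose 2.47-fold and the nucleoside transporter gene SLC29A1 fell 2.15-fold. The cation transporter genes SLC22A3 and SLC29A4 were below the level filter. SLC22A3 had 0.155 ± 0.0330 FPKM with PBS and 0.398 ± 0.0629 with metformin, and SLC29A4 had 0.0888 ± 0.0132 and 0.151 ± 0.0310. SLC47A1, a transporter that exports metformin, was listed at 0 in every library.

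**Figure D3:**
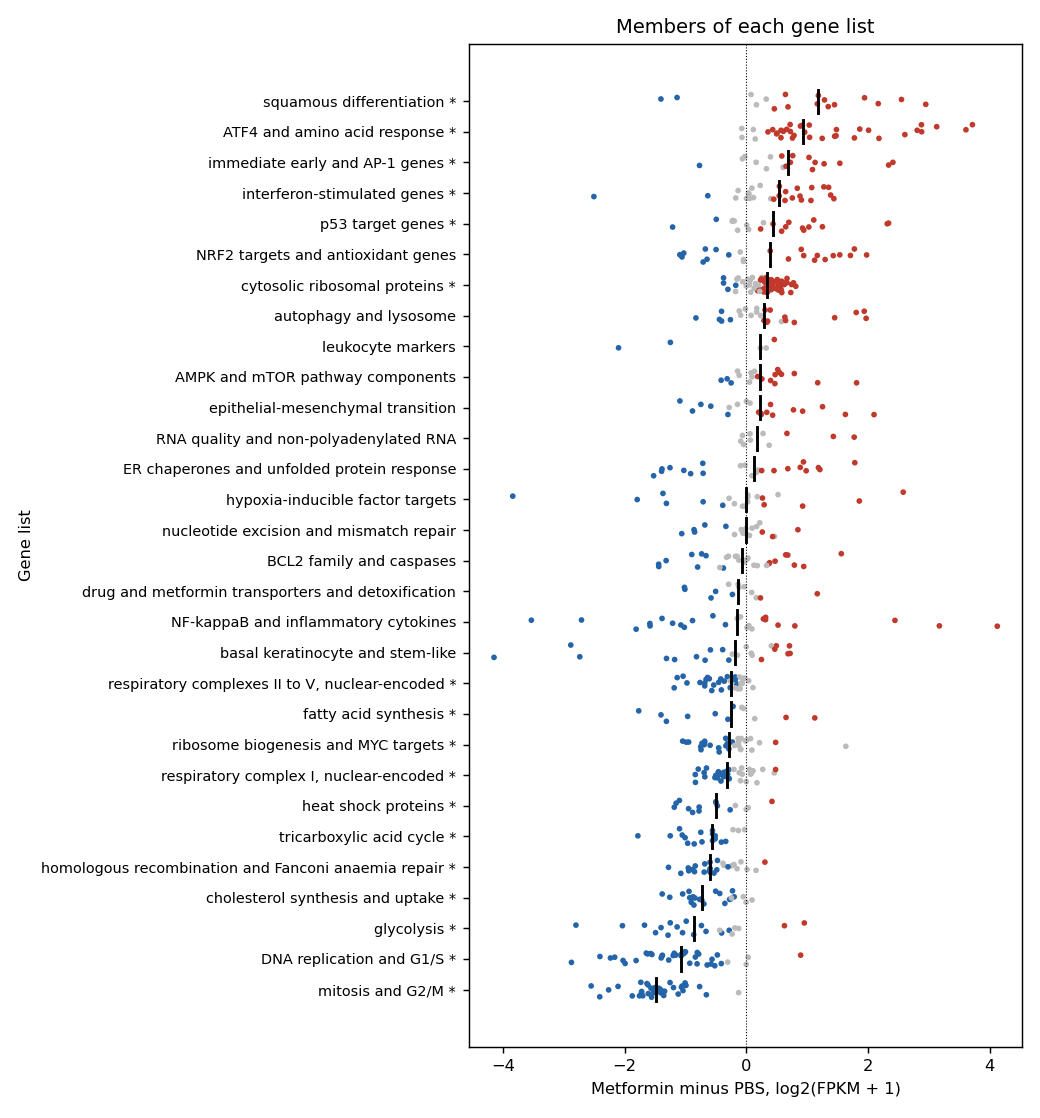
Change with metformin of every tested member of the 30 gene lists, as a difference of log2(FPKM + 1), with red points higher and blue points lower at an adjusted p below 0.05 by limma, grey points not passing, and black bars at list medians. Stars mark the 17 lists that camera called with its preset correlation, from mitosis and G2/M (median -1.49) to squamous differentiation (median 1.17).

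Markers of other cell types gave no common direction. Of 14 fibroblast markers, 4 were tested, 2 higher and 2 lower, with PDPN 2.76-fold and FBLN1 1.73-fold lower, and basal keratinocytes also make PDPN. Of 15 leukocyte and blood markers, 5 were tested, 1 higher and 2 lower (camera adjusted p = 0.354), and the median was 0.23 while the mean was -0.47, the sign that camera gave. LAPTM5 fell 5.53-fold from 14.8 ± 0.994 and CD14 3.93-fold from 3.71 ± 1.09. The only tested endothelial marker, CDH5, fell 3.04-fold from 6.17 ± 0.516, and both tested hepatic and neural markers did not pass. Among transcripts that report on RNA quality, which include RNAs without a poly(A) tail, 3 of 10 were higher and 0 lower (camera adjusted p = 0.310). The nuclear RNA MALAT1 rose 3.50-fold from 26.2 ± 2.30 to 91.7 ± 0.980, and the histone gene HIST1H2BC rose 3.22-fold.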

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

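The test of other splits and the alternatives without both libraries numbered 3 and with protein-coding genes alone were chosen after seeing the data. The count of 7549 genes stayed within 1.5 times under every alternative but a filter at a mean of 5 FPKM, which tested fewer genes and gave 4738, with 877 changed at least 2-fold on the log scale used (427 higher and 450 lower, and 733 and 715 with quantile normalization). A pseudocount of 0.01 gave 2320 genes changed at least 2-fold in place of 1512, since it shrinks low values less. Leaving out 1 library at a time gave 6621 to 6910 genes, with 1461 to 1534 changed at least 2-fold, and no list call changed. Without both libraries numbered 3 the counts were 6045 and 1549. Median-of-ratios and quantile scaling moved the share of higher genes among calls from 55.2% to 48.3% and 48.9%. Of the values of named genes under an alternative, 2129 kept direction and call, 1 lost its call (NDUFB9, given above) and 0 reversed. The replicate block gave 7139 genes. Deviations of same-numbered libraries correlated between -0.01 and 0.03, and not every library correlated best with its own number, so the numbers were not taken to pair libraries. With 10 splits of the libraries no share under 0.05 can be reached: 1 split, the real one, gave 7549 genes and 1512 changed at least 2-fold, and the highest other split gave 2 for each.

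Of 628 list tests under an alternative, 598 kept direction and call. With an estimated correlation, adjusted p was 0.459 for cytosolic ribosomal proteins and interferon-stimulated genes, 0.155 for fatty acid synthesis, 0.147 for heat shock proteins, p53 targets and squamous differentiation, 0.338 for complex I and 0.218 for complexes II to V. A mean of at least 5 FPKM gave 0.183 for squamous differentiation. AMPK and mTOR components passed with that filter (0.0461), with no filter (0.017), with protein-coding genes alone (0.0457) and with quantile normalization (0.0452). Autophagy and lysosome genes passed with no filter (0.0228) and quantile normalization (0.0452), and NF-kappaB genes with no filter (0.0256). The fry test, which asks whether members move one way on balance and compares them with no other genes, gave 0.00019 for AMPK and mTOR, 0.00688 for ER chaperones, 0.00265 for NF-kappaB, 0.000657 for NRF2, 0.0043 for RNA quality, 0.000162 for autophagy, 8.98e-05 for basal keratinocyte, 0.000145 for transporters, 0.000723 for epithelial-mesenchymal transition, 0.04 for hypoxia, 0.00149 for leukocyte and 0.0392 for excision and mismatch repair. Uncalled lists turned direction with a mean of 5 FPKM (BCL2 and caspases, higher, 0.559) and quantile normalization (ER chaperones, higher, 0.849). The cause of these differences was not tested. The files give no fragment counts, so the precision that depth allows for single genes was not computed.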

Other observations

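The gene groups of the first paragraphs, 11 lists tested with camera, and the genes in this part that the report does not name were chosen after their values were seen. The camera p-values of these lists were adjusted over the 11 alone. Because of that choice they describe the same values and are no independent evidence. Of 23 listed genes of actins, tubulins and their partners, 18 were lower with metformin and 0 higher (median log2 change -0.75, camera adjusted p = 1.31e-07, and adjusted p = 0.0202 with an estimated correlation). The microtubule-associated MAP1B, which is not in this list, rose as given above. The tubulin gene TUBB fell from 434 ± 11.1 to 85.3 ± 2.60 FPKM and STMN1, a microtubule-destabilizing protein, from 27.8 ± 0.834 to 8.04 ± 0.282. SR splicing factors and hnRNPs were lower in 17 of 21 and higher in 1 (median -0.69, camera adjusted p = 1.09e-07, and adjusted p = 0.0202 with an estimated correlation), led by HNRNPA1, which fell from 165 ± 3.03 to 44.3 ± 1.54. Pentose phosphate and nucleotide synthesis genes were lower in 15 of 22 and higher in 1 (camera adjusted p = 7.3e-05, and adjusted p = 0.0362 with an estimated correlation). TALDO1, the transaldolase, fell from 80.6 ± 2.32 to 38.2 ± 3.41. Proteasome subunits were lower in 27 of 32 and higher in 1 (camera adjusted p = 1.11e-08, and adjusted p = 0.0582 with an estimated correlation), and PSMD13 fell from 26.1 ± 2.71 to 10.5 ± 0.147. All 8 genes of the CCT chaperonin, which folds actin and tubulin, were lower (camera adjusted p = 9.9e-05, and adjusted p = 0.0582 with an estimated correlation).

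Ligands of the epidermal growth factor receptor were higher in 4 of 5 and lower in 0 (median 0.92, camera adjusted p = 0.00182, and adjusted p = 0.0582 with an estimated correlation), where HBEGF rose from 21.8 ± 1.36 to 49.2 ± 0.644 FPKM beside AREG. Host genes of small nucleolar RNAs were higher in 8 of 13 and lower in 0 (camera adjusted p = 0.00776, and adjusted p = 0.211 with an estimated correlation), and GAS5 rose from 20.1 ± 0.231 to 115 ± 8.37. S100 protein genes gave 6 lower and 2 higher of 12 (camera adjusted p = 0.0306, and adjusted p = 0.223 with an estimated correlation), with S100A9, a calprotectin subunit, falling from 459 ± 42.2 to 80.5 ± 2.10. Mitochondrial ribosomal protein genes were lower in 24 of 54 and higher in 2 (camera adjusted p = 0.000178, and adjusted p = 0.162 with an estimated correlation). Zinc finger genes with numbered ZNF names were higher in 70 of 223, a share close to the 4169 of all 13437 tested genes, and lower in 22, a smaller share than the 3380 of all tested genes (camera adjusted p = 0.036, and adjusted p = 0.223 with an estimated correlation). MHC class I presentation genes gave 4 higher and 1 lower of 12 (camera adjusted p = 0.472), with HLA-B at 131 ± 18.7 and 193 ± 3.02. Of 379 long intergenic noncoding RNAs, 172 were higher and 42 lower (median 0.37), and of 1047 antisense genes 362 were higher and 144 lower (median 0.21), against 3251 higher and 3052 lower of 10801 protein-coding genes (median 0.02). These gene types were not matched for level. With genes averaging at least 5 FPKM, 50.7% of calls were higher, against 55.2% of calls in the main fit, so level and type cannot be told apart here. In 930 pairs of an antisense gene and a protein-coding gene whose exons overlap, the log2 changes correlated with r = 0.62 across pairs, which are not independent replicates, so part of the antisense values cannot be separated from the coding gene.

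The GAPDH transcript, often used as a reference in expression assays, fell from 1146 ± 53 to 432 ± 8.79 FPKM, and ACTB fell from 863 ± 35.5 to 437 ± 7.69.

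In the tests of the 3 patterns below, those of a shared batch and of the chromosome 1 pseudogenes were chosen after the result was seen. Haemoglobin transcripts were high in both libraries numbered 3. HBB had 84.9 FPKM in PBS replicate 3 and 109 in metformin replicate 3, against 8.66 to 18.1 in the other 4 libraries, and in the means HBA1, HBA2 and the 7SK RNA gene RN7SK were 8.74-fold, 8.75-fold and 4.43-fold higher there. RNA of blood cells remains open: 5 of 31 other blood genes were highest in both libraries (16.1% against 6.67% by chance, one-sided exact binomial p = 0.0524, and 4.1% of 1415 protein-coding genes at matched levels), all at or below 0.349 FPKM. A shared preparation or sequencing batch, which the labels do not give, also remains open: 10 of 130 small structural RNA genes other than 7SK, 7SL and RNase P RNA were highest in both (one-sided exact binomial p = 0.367 against 1 in 15), with 4 highest in both libraries numbered 1 and 5 in both numbered 2, so the test neither shows nor excludes it. A first comparison against protein-coding genes, of which 1.58% were highest in both, was set aside because group differences lower that share, and no biological explanation was tested because the number is not a treatment. For genes that differ between the groups, 1 in 15 is likewise too high a chance share. Both binomial p-values may therefore be too large, and neither decides its question.

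In a block of 7 mitochondria-like pseudogenes on chromosome 1 (629062 to 634922, GRCh38), 5 were lower with metformin although the mitochondrial genes themselves were listed at 0. MTCO1P12 fell from 1069 ± 25.5 to 399 ± 13.2 FPKM, MTATP6P1 from 798 ± 109 to 417 ± 6.38 and MTCO3P12 from 73.3 ± 14.1 to 25.3 ± 0.368, while MTND1P23 had 125 ± 21.8 and 155 ± 6.96 and MTATP8P1 17.1 ± 2.63 and 14.7 ± 12.6, and neither passed. A single nuclear transcript across the block would change all members alike, which the tables argue against: MTND1P23 and MTCO3P12 differed by 1.80 on the log2 scale, 10.1 times the error of that difference. Fragments of mitochondrial transcripts listed under these near-identical copies may account for the values, since every member lay at or above the 78.2 percentile of expressed genes in PBS, but high levels of the copies themselves would look alike. A fall of mitochondrial transcripts under metformin thus remains an untested possibility.

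Of 67 cytosolic ribosomal protein genes, 48 were higher and 4 lower, a list call that was lost with an estimated correlation (adjusted p = 0.459). For a shift of the metformin libraries toward short transcripts, protein-coding genes of matched exonic length had a median log2 change of 0.04. That lay below the 25th percentile of the ribosomal protein genes at 0.19. The length covered the exons of all annotated isoforms and can exceed that of the expressed transcript, so this check does not exclude such a shift. A shift toward abundant transcripts is argued against by genes of matched level, whose median was -0.20. Length and level were matched separately, so a shift of transcripts both short and abundant was not tested. A move of fragments from listed pseudogenes to the genes is argued against by the small share of these pseudogenes. In 58 genes they made up a median of 0.2% of the sum of gene and pseudogenes in PBS. The sum rose by a median of 0.35, which follows from that share and is no separate test. Fragments left out before the values were made are not covered. A coordinated response of these genes to metformin may be involved and stays a hypothesis, given the lost call.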
